A study of Notophthalmus viridescens with 3 samples.

How the data were processed

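Total RNA from whole newt hearts (Notophthalmus viridescens) was extracted with a kit that retains small RNA, per the labels' protocols. The labels give 2.6, 5.1 and 3.3 µg of RNA for the uninjured, 7 dpi and 21 dpi samples sent to a service provider, and 0.5 µg as the input of each assay. RNA was tailed with an adapter that carries a tag for staining with the dye Cy3. The series design text speaks of samples compared in pairs on arrays, while each scanner file used here holds 1 channel of 1 sample, and the values were treated as 1-colour. How many animals each sample holds is not stated in the labels. Probes were made for human, zebrafish and frog miRNAs, so newt miRNAs that differ from these are read through mismatched probes or missed. No newt genome was used here, and no genomic positions are given.

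Each array had 5022 spots, of which 4095 were 3 replicate spots of 1365 miRNA probes and 587 were empty. Spot brightness is the deposited median intensity on a linear scale, per the file headers, with no local background column. Image software is not given in the sources used here. The authors also deposited 1 processed intensity per probe. From its values it is linear, background subtracted and scaled between arrays, by a method not given in the sources used here. On the log2 scale it had Pearson correlations of 0.98, 0.96 and 0.99 with the values computed here before normalization. These correlations cover the probes detected on each array. The array medians of the processed intensity were 1.49, 0.807 and 2.40. It served as an alternative.

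Intensities were background corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, fitted on all spots. The design fixed before the data were examined foresaw a background column, and normexp was fitted on the foreground alone because there is none. For the same reason the alternative of plain subtraction used the median of the empty spots, 68.0, 71.7 and 71.4 on the 3 arrays. Values were put on the log2 scale, averaged over the 3 spots and quantile normalized over the miRNA probes. Quantile normalization assumes a like distribution of miRNA signal in each sample. The offset compresses differences of dim probes. Alternatives that scale a whole array were applied after the offset, so they also shift probes near the empty spots. A probe was detected where its median spot exceeded percentile 95 of the empty spots of its array. Probes of 1 miRNA name from several species were collapsed to the probe with the highest mean signal, giving 1242 names. The zebrafish probe of miR-21 was near the empty spots on the uninjured and 7 dpi arrays, so its size disagrees with that of the human probe used.

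A miRNA was called different where the log2 difference was at least 1 in size, it was detected on at least 1 of the 2 arrays, and the 3 spots of each array did not overlap. No significance test is possible with 1 sample per group, and the number of arrays limits the precision. A miRNA detected on 1 array only has a lower bound, its level against the higher of the detection level and its own level on the other array. The rule for named miRNAs, also fixed before the data were examined, took the 10 brightest in the uninjured heart, the 10 largest differences in each direction among miRNAs detected on both arrays without overlap, up to 5 detected on 1 array only, and up to 4 of the brightest members of each list. Lists were striated muscle, smooth muscle, let-7, miR-17/92, miR-15/16, miR-29, miR-30, fibroblast and injury, miR-128, miR-23/27/24, miR-99 with miR-100, miR-125 and miR-10, miR-101, miR-26, leukocyte, erythroid, endothelial, epithelial, neural, liver and embryonic. The median difference of the detected members was placed among 10000 random lists of the same size drawn from the 30 miRNAs nearest in mean signal to each member. In an alternative added after seeing the data, probes whose sequences matched with at most 1 mismatch over at least 18 bases, at a shift of at most 2 bases, were linked, and the brightest probe of each linked group was kept in the lists and in the random pool. Lists with fewer than 3 detected members were given as values. These percentiles describe the arrays and are not p-values.

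The calling step was tested on simulated data run on 1365 probes. Signals came from the uninjured array, and the simulated 7 dpi array held them dimmed by 1 common factor. Spot noise was added, but no failed spots, no variation between samples and no shift between probe classes. Of 15 miRNAs simulated 3-fold higher it called 7, of 15 simulated 3-fold lower 8, of 15 simulated 6-fold higher 13 and of 15 simulated 6-fold lower 10, none in the wrong direction. It called 1 of 164 detected miRNAs simulated without a difference, which does not measure false calls between real samples. Alternatives covered normalization, background correction, offset, detection, spot summary, threshold, species collapse and the authors' values. Scaling to 5S rRNA or spike-in probes, removal of a GC trend, detection at the median plus 3 median absolute deviations, and detection on both arrays were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.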

Results

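MicroRNA levels were measured in whole hearts of adult red-spotted newts, salamanders that regrow heart muscle after injury. One sample came from an uninjured heart preparation, 1 from 7 days post injury (dpi) and 1 from 21 dpi, each read on 1 array. The comparisons address how miRNA levels differ between the resting heart and an early and a later time of regeneration. With 1 sample per group there is no replicate check, no p-value is given, and each comparison describes these samples. Differences are on the log2 scale of normalized signal, and each ± is the standard error over the 3 replicate spots of a probe on both arrays, which is technical spread only. Of 1242 miRNA names on the array, 186 were detected in the uninjured heart, 184 at 7 dpi and 147 at 21 dpi, and 138 were detected in all 3 samples. The detection minimum was a spot intensity of 73.8, 77.5 and 103 on these arrays, so the lower number at 21 dpi goes with a higher minimum. Across those 138 miRNAs, which are not independent replicates, normalized signals of the uninjured and 7 dpi arrays had a Pearson r of 0.92, those of the uninjured and 21 dpi arrays 0.96, and those of the 7 and 21 dpi arrays 0.92.

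In the uninjured heart the brightest probe was miR-1826, at 15.19 log2 units. It held the top rank on all 3 arrays, which rank-based normalization sets to a difference of 0. It was followed by the striated-muscle miRNA miR-1 at 13.05 ± 0.11 (SD of 3 spots), and by let-7a at 12.80 ± 0.12, let-7d at 12.51 ± 0.11 and let-7f at 12.35 ± 0.14. The other members of the top 10 were miR-1a at 12.25, miR-23b at 12.10, miR-125a at 12.02, miR-26a at 11.96 and miR-26 at 11.89. Probes of near-identical family members can capture each other's targets, so signal within the let-7, miR-1, miR-26, miR-125, miR-15/16 and miR-17/92 families cannot be assigned to a single member.

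Before normalization, the 7 dpi array was dimmer for most miRNAs. The median signal above the empty spots of the 138 miRNAs was 411 in the uninjured heart, 148 at 7 dpi and 553 at 21 dpi. The median log2 ratio to the uninjured heart was -1.38 at 7 dpi, with 90.6% of the 138 miRNAs lower, and 0.38 at 21 dpi. Over the same arrays, 14 probes for 5S rRNA had median log2 ratios of -0.10 and 0.35, and 16 spike-in probes 0.46 and 1.46. The brightest probe, miR-1826, stood at 0.09 and 0.23, nearer at 7 dpi to the 5S rRNA median than to the miRNA median. Whether its signal comes from a miRNA was not tested. Normalization brought the median difference of the 138 miRNAs from -1.09 to -0.08 at 7 dpi and from 0.34 to 0.00 at 21 dpi on the background-corrected log2 scale. Every difference below is relative to that shift.

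**Figure D1:**
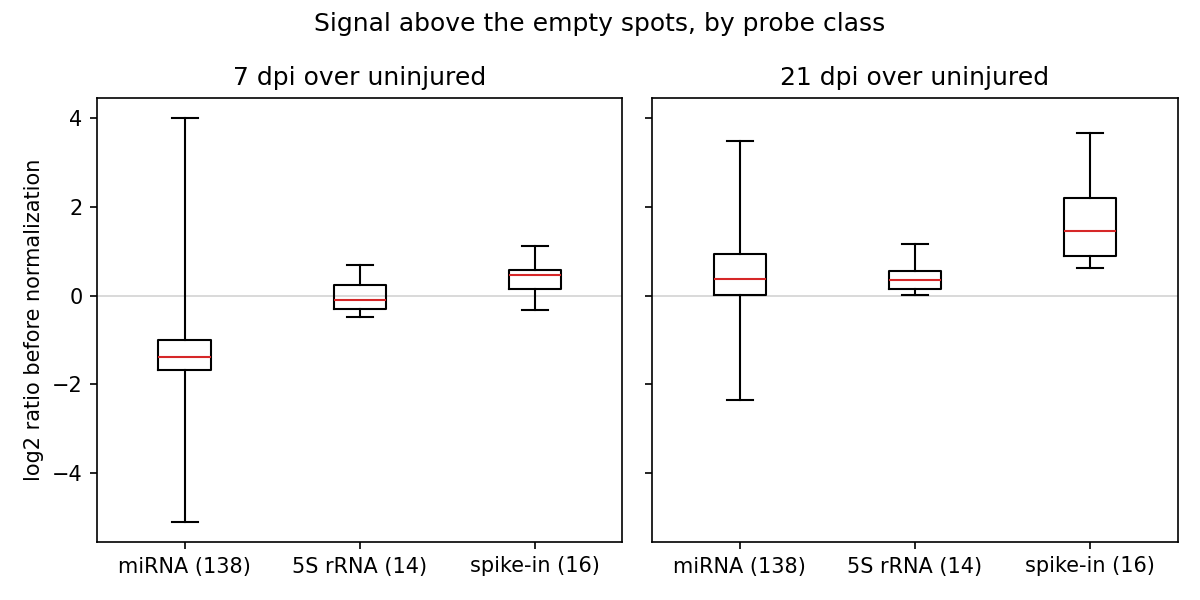
Log2 ratio of signal above the empty spots before normalization, at 7 dpi (left) and 21 dpi (right) over the uninjured heart, for miRNAs detected on all arrays and for 5S rRNA and spike-in probes, with the number of items in brackets; boxes span the quartiles, red lines mark medians and whiskers reach the extremes. At 7 dpi the miRNA median lies at -1.38 and the 5S rRNA median at -0.10.

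At 7 dpi, miR-21, miR-155 and miR-223 were higher than in the uninjured heart, and miR-1b and miR-16b were lower. The miRNA miR-21 (UAGCUUAUCAGACUGAUGUUGA), which is raised in many injured tissues, was higher by 1.76 ± 0.13. The leukocyte miRNAs miR-155 and miR-223 were higher by 1.51 ± 0.38 and 1.48 ± 0.09. The miR-223 probe read 31.3 above the empty spots in the uninjured heart and 95.5 at 7 dpi, and a second, dimmer probe of miR-223 stood at 0.09. Among miRNAs whose spots did not overlap, the lowest value belonged to miR-1b (UGGAAUGUUAAGAAGUAUGUA), a striated-muscle miRNA, at -2.22 ± 0.07. The brighter and near-identical miR-1a and miR-1 stood at -0.83 and -0.25, so the size of the miR-1b difference cannot be assigned to miR-1b alone. Whether harsher hybridization of the 7 dpi array set the miR-1b probe apart was not tested. Of 212 miRNAs detected on at least 1 of these arrays, 18 were at least 2-fold higher and 4 at least 2-fold lower with no overlap between spots.

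Among miRNAs detected on both arrays, the largest positive difference at 7 dpi was that of miR-466 (AUACACAUACACGCAACACACAU), at 3.33 ± 0.07. Other higher miRNAs in this group were miR-762 at 2.06 ± 0.15, miR-574-3p at 1.89 ± 0.10, miR-197 at 1.88 ± 0.09, miR-1469 at 1.66 ± 0.12, miR-1976 at 1.41 ± 0.07 and miR-1260 at 1.33 ± 0.04. Of the 18 higher miRNAs, 13 have no frog or zebrafish probe of the same number on the array, against 64 of the 212 tested. The median GC content of the target sequences was 60.1% among all 18 higher miRNAs, 42.7% among the lower and 47.8% among those tested. The liver miRNA miR-122 was detected at 7 dpi and not in the uninjured heart, at least 2.98-fold higher. Such bounds were 4.59-fold for miR-187, 2.51-fold for miR-328, 2.38-fold for miR-885-5p and 2.10-fold for miR-1228. On the lower side, miR-139 stood at -1.19 ± 0.06, miR-16b at -1.11 ± 0.08, miR-148b just short of the threshold at -0.997 ± 0.09, miR-133a* at -0.92 ± 0.08 and miR-4298 at -0.88 ± 0.21. miR-128 (UCACAGUGAACCGGUCUCUUU), fixed beforehand as a list of its own, stood at -0.86 ± 0.10, miR-199a-3p at -0.86 ± 0.71 (-0.13 in the authors' values), miR-1a at -0.83 ± 0.13 and miR-16a at -0.82 ± 0.10. The miRNA miR-184 was detected only in the uninjured heart, at least 2.42-fold above 7 dpi.

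Among the lists fixed beforehand, the miR-15/16 family, whose members restrain the cell cycle, had a median of -0.53 at 7 dpi, at percentile 0.17 of random lists of matched signal, with 5 of 8 detected members lower. Several of its probes are near-identical and share signal. When such probes were merged to the brightest one, in the lists and in the random pool, 5 members were left with a median of 0.31 at percentile 83.9, so no difference of this family is claimed. The miR-15c value within it, 0.70 ± 0.43, was 0.18 with the median of spots. The endothelial miR-126 list had a median of -0.66, at percentile 1.21, but this is the value of miR-126b*, which like miR-126b was not detected at 7 dpi and was at least 1.22-fold higher in the uninjured heart. The third member, miR-126, stood at -0.17 ± 0.09 with overlapping spots. With the empty-spot median subtracted and a floor of 32 the list median was -0.19, at percentile 38.1, so no difference of this list is claimed. The medians of these lists turned positive, at 0.25 and 0.20, when arrays were scaled to the median of the miRNAs detected on all 3. That scaling followed the offset and also raised probes near the empty spots at 7 dpi, such as miR-126b, to 0.20. The leukocyte list had a median of 1.11 at percentile 96.5, inside the central range, with 3 of 4 members higher, and miR-150 at 0.75 ± 0.09. The striated-muscle list had a median of -0.24 at percentile 3.08, with 7 of 12 members lower. Its members miR-133a and miR-133b were at 0.35 ± 0.11 and 0.34 ± 0.12, against -0.25 ± 0.07 for miR-1, but the frog probes of miR-133a and miR-133b went the other way, at -0.15 and -0.29. Rank-based normalization sets the size of the miR-1 value, since miR-1 and let-7a exchanged ranks. Before normalization the miR-1 ratio above the empty spots was -1.90, beside a median of -1.38, and in the authors' values miR-1 stood at -0.75. The list of miR-99, miR-100, miR-125 and miR-10 had a median of -0.33 at percentile 2.76, and miR-125b within it stood at 0.24 ± 0.07.

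The other lists lay well inside the random range at 7 dpi. Medians were -0.15 for let-7 (11 detected members), 0.00 for the miR-17/92 family (17), -0.13 for miR-29 (4), -0.18 for miR-30 (6), -0.03 for the fibroblast and injury list (7), 0.00 for miR-23/27/24 (10), -0.17 for miR-101 (3) and -0.09 for miR-26 (3). The erythroid list had a median of -0.08 (3 members) and the epithelial list -0.05 (5). Scaled to the median of shared miRNAs, the miR-29, fibroblast and injury, erythroid and epithelial medians turned positive, at 0.19, 0.43, 0.84 and 1.10. The smooth-muscle miRNAs miR-145 and miR-143 were at -0.67 ± 0.09 and -0.23 ± 0.04, and at 0.31 and 0.88 when scaled to the median of shared miRNAs. That scaling followed the offset and also raised dim probes at 7 dpi. Before normalization, the ratios above the empty spots were -2.06 for miR-145 and -1.29 for miR-143, beside a median of -1.38. No member of the neural or embryonic lists was detected on any array.

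Scaling sets the split of these calls, while miR-21, miR-155, miR-223, miR-466 and miR-1b kept their direction under every scaling tried. With no normalization 6 miRNAs were higher and 77 lower at 7 dpi, with 5S rRNA scaling 10 and 71, with spike-in scaling 2 and 99, and with scaling to the median of shared miRNAs 60 and 5. The last of these scalings followed the offset, so it also raised dim probes at 7 dpi. Of the 4 lower calls, 2 were kept with cyclic loess and 2 with scaling to the median of shared miRNAs. The miR-155 difference rests in part on 1 dim spot in the uninjured heart, at 5.05 above the empty spots against 82.7 and 94.2 for the others.

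**Figure D2:**
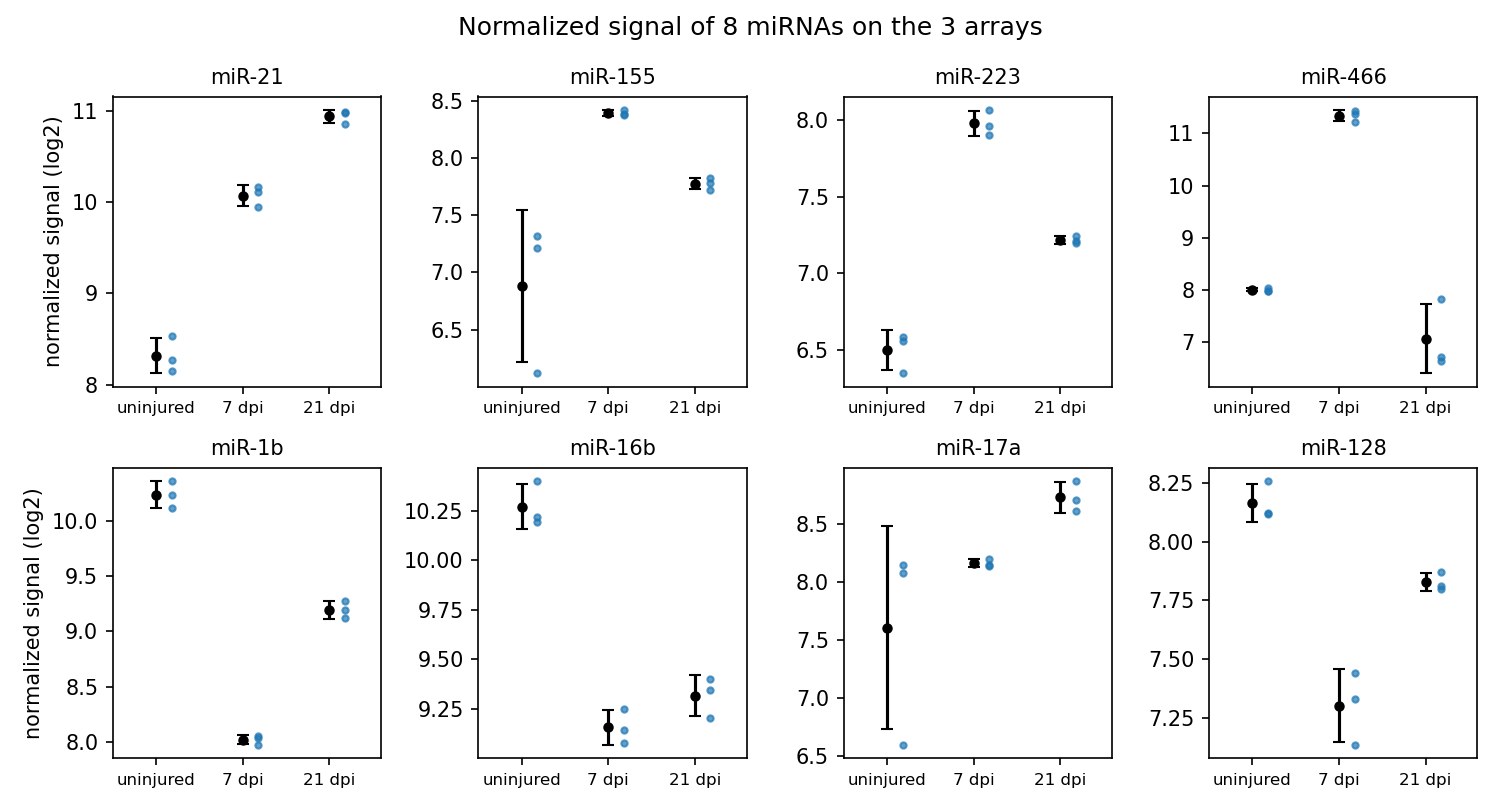
Normalized log2 signal of 8 miRNAs on the uninjured, 7 dpi and 21 dpi arrays; black points are means with the SD of 3 replicate spots, blue points are the spots, and each panel has its own axis. The miR-21 level is higher by 1.76 at 7 dpi and by 2.62 at 21 dpi than in the uninjured heart, and the miR-1b level is lower, at -2.22 and -1.04.

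At 21 dpi, 5 miRNAs were called against the uninjured heart, compared with 22 at 7 dpi, an order that spike-in scaling reversed (139 and 101). Of these, miR-21 stood furthest above it, at 2.62 ± 0.12. Within the growth-associated miR-17/92 family, 1 of 17 detected members passed 2-fold, miR-17a at 1.12 ± 0.51, while miR-106a at 0.81 ± 0.14 and miR-20b at 0.81 ± 0.08 stayed below it. The muscle miRNA miR-1b was lower, at -1.04 ± 0.08, while the brighter and near-identical miR-1 stood at 0.00 ± 0.08, with the same rank on both arrays. Rank-based normalization sets this value of miR-1. Before normalization its ratio above the empty spots was -0.79, beside a median of 0.38 over the 138 miRNAs. By the median spot let-7a was brighter than miR-1 at 21 dpi, at 10790 against 8330 above the empty spots. However, 1 of the let-7a spots was dim, at 2652, which lowered its mean. Of 190 miRNAs tested, 2 were at least 2-fold higher, miR-21 and miR-17a, and 3 at least 2-fold lower, miR-1b, miR-184 and miR-4267. The last pair was not detected at 21 dpi, and was at least 2.17-fold higher in the uninjured heart for miR-184 and 2.28-fold for miR-4267.

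Further positive differences at 21 dpi were those of miR-1280 at 0.95 ± 0.11, miR-155 at 0.89 ± 0.39, miR-720 at 0.79 ± 0.08, miR-92b at 0.74 ± 0.39, and the clustered pair miR-222 and miR-221 at 0.78 ± 0.12 and 0.78 ± 0.19. On the lower side were miR-133a* at -0.99 ± 0.09, miR-16b at -0.95 ± 0.09, miR-466 at -0.94 ± 0.38, miR-4298 at -0.81 ± 0.20 and miR-140* at -0.65 ± 0.12. The remaining named miRNAs were miR-4281 at -0.62 ± 0.23, miR-3141 at -0.61 ± 0.15, miR-26b at -0.59 ± 0.43 and miR-1973 at -0.53 ± 0.21. In the authors' values miR-26b stood at -0.07. The leukocyte miRNA miR-142-3p was detected at 21 dpi and not in the uninjured heart, at least 1.55-fold higher. miR-128 stood at -0.34 ± 0.05.

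The miR-17/92 family had a median of 0.36 at 21 dpi, at percentile 98.7 of random lists, with 11 of 17 detected members higher. With near-identical probes merged, 8 members were left with a median of 0.33 at percentile 91.6, inside the central range. The leukocyte list had a median of 0.72 at percentile 99.7, and 99.8 with the merged pool, with 4 of 5 members higher, among them miR-223 at 0.72 ± 0.08. None of its members was called at 2-fold, and with no detection filter no list lay outside at 21 dpi. The miR-17/92 and leukocyte medians turned negative, at -0.71 and -0.53, when arrays were scaled to the spike-in probes. So did miR-20b at -0.41, miR-106a at -0.12, miR-155 at -0.08, miR-222 at -0.47, miR-221 at -0.60, miR-1280 at -0.45, miR-720 at -0.46, miR-92b at -0.37, miR-142-3p at -0.47, miR-223 at -0.53 and miR-499 at -0.97. This scaling followed the offset, so at 21 dpi it also lowered probes with little or no signal. An example is miR-142-3p, which was not detected in the uninjured heart. In ratios of signal above the empty spots, miR-223 at 1.89, miR-106a at 1.84 and miR-155 at 1.66 exceeded the spike-in median of 1.46. The ratios of miR-20b, miR-222, miR-221, miR-1280, miR-720, miR-92b and miR-499 lay below it. That median includes 4 mismatch probes of the spike-ins, at 2.11 to 3.67, and the match probes alone were not used as a reference. The striated-muscle list was near 0, with a median of 0.03 over 12 members. Within it miR-499 was at 0.44 ± 0.03 and miR-1a at -0.43 ± 0.05. The smooth-muscle miRNAs miR-145 and miR-143 were at 0.45 ± 0.10 and 0.35 ± 0.10, and at -0.58 and -0.89 with spike-in scaling, and 1 other probe of miR-145 was at -0.05. Medians were -0.24 for let-7, -0.20 for miR-15/16, -0.13 for miR-29, -0.01 for miR-30, -0.06 for the fibroblast and injury list, 0.14 for miR-23/27/24, -0.36 for the list of miR-99, miR-100, miR-125 and miR-10, -0.08 for miR-101 and -0.21 for miR-26. The erythroid list had a median of 0.00, the endothelial list -0.25 and the epithelial list -0.10. Liver miR-122 was not detected at 21 dpi.

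The miR-17a call rests on 1 dim spot in the uninjured heart, at 33.4 above the empty spots against 206 and 220, and it is lost when the median of spots replaces the mean. With no normalization 17 miRNAs were higher and 1 lower at 21 dpi, and with spike-in scaling 1 and 138.

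**Figure D3:**
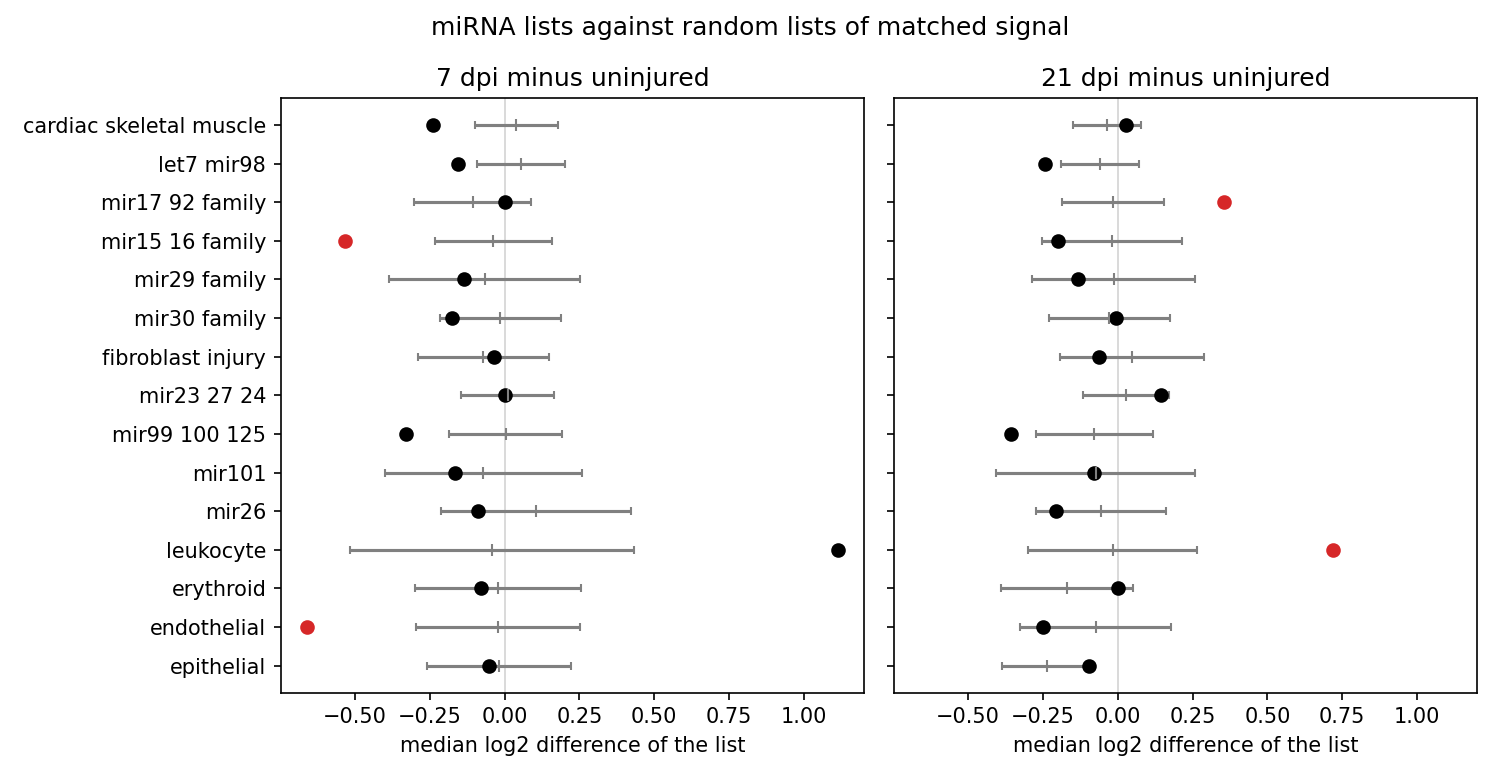
Median log2 difference of each miRNA list with at least 3 detected members (points), at 7 dpi (left) and 21 dpi (right) against the uninjured heart, beside the median and SD of 10000 random lists of matched signal (grey); red points lie outside the central 95% of random lists. The red points are miR-15/16 at -0.53 and endothelial at -0.66 at 7 dpi, and miR-17/92 at 0.36 and leukocyte at 0.72 at 21 dpi; the endothelial point is the value of miR-126b*, which was not detected at 7 dpi. With near-identical probes merged, the leukocyte point stayed outside, miR-15/16 and miR-17/92 did not, and the endothelial list had too few members. With no detection filter, no list lay outside at 21 dpi.

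Between the injured hearts, the muscle miRNA miR-1b and the smooth-muscle miRNA miR-145 were at least 2-fold higher at 21 dpi than at 7 dpi, and miR-466, miR-574-3p and miR-762 were lower. The miR-1b difference was 1.18 ± 0.05 and that of miR-145 was 1.12 ± 0.11. Both were below 2-fold with cyclic loess, at 0.91 and 0.76, and with scaling to the median of shared miRNAs, at 0.82 and 0.34, where 1 of the 6 higher calls was kept in each case. The brighter and near-identical miR-1 stood at 0.25, and at -0.62 with cyclic loess. On the other side, miR-466 stood at -4.27 ± 0.39. Of 193 miRNAs tested, 6 were at least 2-fold higher at 21 dpi and 17 at least 2-fold lower, and the lower ones had a median GC content of 68.2%. Of those 17, 14 have no frog or zebrafish probe of the same number.

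The other higher miRNAs were miR-499-5p at 1.72 ± 1.31, miR-92a at 1.17 ± 0.52, miR-125a-5p at 1.17 ± 0.11 and miR-107b at 1.02 ± 0.53. The values for miR-499-5p, miR-92a and miR-107b each rest on 1 dim spot at 7 dpi, at 41.7, 2.84 and 13.3 above the empty spots, and 3 higher calls were kept when the median of spots replaced the mean. Below 2-fold were miR-139 at 0.88 ± 0.07, miR-21 at 0.87 ± 0.08, miR-494 at 0.85 ± 0.09 and miR-199a-3p at 0.84 ± 0.71. The 7 dpi spots of miR-199a-3p part, and its difference was -0.10 in the authors' values. Lower miRNAs were miR-574-3p at -1.89 ± 0.11, miR-762 at -1.80 ± 0.07, miR-24b at -1.66 ± 0.76, miR-197 at -1.47 ± 0.23, miR-1469 at -1.45 ± 0.11, miR-3141 at -1.37 ± 0.10, miR-638 at -1.22 ± 0.15, miR-3196 at -1.03 ± 0.11 and miR-663 at -0.87 ± 0.08. The miR-24b value rests on spots that part at 21 dpi, at 399, 432 and 2279 above the empty spots. Detected at 7 dpi and not at 21 dpi, miR-187 was at least 4.01-fold, miR-122 at least 2.60-fold and miR-1976 at least 2.44-fold higher there than at 21 dpi. No list lay outside the central range of random lists in this comparison. The miR-17/92 family came nearest, with a median of 0.49 at percentile 94.3. Over all comparisons 4 of 44 list medians lay outside, the endothelial one included, where 2.2 would if each list behaved like its random lists. That number is a loose guide, since near-identical probes of a family share signal and the comparisons share arrays. With near-identical probes merged, the list of miR-99, miR-100, miR-125 and miR-10 at 21 dpi lay outside, at percentile 2.21, beside the leukocyte list. With no normalization 100 miRNAs were higher and 4 lower at 21 dpi than at 7 dpi, and miR-3196, miR-1469 and miR-663 had the opposite sign, at 0.35, 0.086 and 0.026.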

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

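All explanations below were tested only after the results were seen, and the limits that decide each test were set then.

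The miRNA miR-466 differed from the uninjured heart in opposite directions at the 2 times after injury, at 3.33 at 7 dpi and -0.94 at 21 dpi, with no overlap between spots in either comparison. The difference between the times was not tested, since there is 1 sample per time. Control probes outside the comparisons also stood above their uninjured level. The spike-in probes had a median log2 ratio of 0.46 at 7 dpi and 1.46 at 21 dpi, and the 5S rRNA probes of 0.35 at 21 dpi. The mismatch probe of 1 spike-in read 18.1% of its match probe in the uninjured heart, 17.4% at 7 dpi and 33.5% at 21 dpi. At 21 dpi the mismatch probe rose more than its match probe in all 4 detected pairs. Log2 ratios to the uninjured heart were 2.11 to 3.67 for mismatch and 0.75 to 1.61 for match probes. Some mismatch probes were dim in the uninjured heart, and all 4 count in the spike-in median of 1.46. Whether looser binding raised miRNA signal read through mismatched probes at 21 dpi was not tested.

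The first pattern is the lower miRNA signal at 7 dpi before normalization, a median log2 ratio of -1.38 over 138 miRNAs. Dimming of all probes alike, by labelling, hybridization or scanning, is argued against by the 5S rRNA probes. Their median was -0.10, and their lower quartile, -0.29, lies above the upper quartile of the miRNAs, -0.998. The 5S rRNA probes cannot exclude harsher hybridization that lowers miRNA probes more than 5S rRNA probes, which was not tested for this pattern. Across the 138 miRNAs, GC content and the normalized difference at 7 dpi had a Spearman correlation of 0.34. Among those with a frog or zebrafish probe of the name it was 0.25. The 5S rRNA median exceeded the miRNA median by 1.28. That gap also leaves open a loss of small RNA from this sample before labelling and a lower miRNA share of total RNA in the heart at 7 dpi. These cannot be told apart with 1 sample per time.

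The second pattern is that 13 of the 18 miRNAs higher at 7 dpi bear names without a frog or zebrafish probe. A linear GC trend alone is argued against because 8 of the 13 calls were kept when it was removed, while 5 ended as the median difference of the 13 went from 1.43 to 1.11. A steeper or non-linear effect of GC content was not tested. Constant signal from other RNA, lifted by normalization, was tested first on all 21 such miRNAs detected on every array, whose median ratio before normalization was -0.29 (quartiles -0.999 and 0.999), beside -0.10 for 5S rRNA. The 13 called miRNAs, tested after that result, had a median of 2.42 (quartiles 1.13 and 3.44) against an upper quartile of 0.25 for 5S rRNA, but they were chosen for being higher, 3 entered at the detection minimum and others were dim in the uninjured heart, such as miR-197 at 6.65 above the empty spots. The sets point different ways, so constant signal cannot be told apart from a higher level at 7 dpi of these small RNAs or of RNA that binds the same probes.

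The third pattern is miR-125c at 7 dpi, at -2.26 with overlapping spots, beside miR-125b at 0.24, whose sequence differs by U18C, counted from the 5′ end with the miR-125b base first. Its 3 spots at 7 dpi read 75.6, 139 and 1938 above the empty spots. The brightest was 1.19 times the miR-125b level, which is consistent with failure of the others. Only 1 of 3 spots reached that level, so a lower miR-125c level with a falsely bright spot stays open. Harsher hybridization also stays open, since 1 mismatch pair of the spike-ins, looked at first, differed by -0.057 log2 from the uninjured array, the 4 detected pairs lay between -0.48 and 0.37 (median 0.048), and 36 of 48 probe pairs with 1 differing base stood further apart at 7 dpi than in the uninjured heart, against 25 at 21 dpi, while the median change of the gap in either direction was 0.271 and 0.278.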

How the results depend on the processing

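The scalings to 5S rRNA and spike-in probes, the GC trend, detection at 3 median absolute deviations, detection on both arrays and the merging of near-identical probes were chosen after seeing the data. The cause of each shift below was not tested, except that stricter filters and the 1.5-fold threshold alter the number of miRNAs that can be called by construction. Scalings by 1 factor per array were applied after the offset, so they also shift dim and undetected probes. Leaving out a sample is not possible with 1 per group. No paired analysis was possible because the labels carry no replicate numbers and each group has 1 sample. Under 2 times the detection minimum, 119 miRNAs were detected in the uninjured heart and 104 at 7 dpi. The brighter part of miRNAs detected on both arrays kept 11 of 22, 3 of 5 and 12 of 23 calls. Counts are given as higher and lower calls at 7 dpi and at 21 dpi against the uninjured heart, then at 21 dpi against 7 dpi, where they moved by over 1.5 times. In this order the main counts are 18 and 4, 2 and 3, and 6 and 17.

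Cyclic loess gave 2 lower at 7 dpi, 14 calls (5 higher, 9 lower) at 21 dpi, 1 higher between the injured hearts and 1 list outside there. Scaling to the median of shared miRNAs gave 65 calls (60 higher) at 7 dpi, 15 (4 and 11) at 21 dpi, 64 (1 and 63) between them and 1 list outside at 7 dpi, with miR-15/16 reversed to 0.25 and the endothelial list to 0.20. Scaling to percentile 75 gave 83 (6 and 77), 16 (13 higher) and 99 (94 and 5), 1 list at 7 dpi, miR-1280 at -0.40 at 7 dpi and miR-3196 at 0.26 between the injured hearts. No normalization gave 83 (6 and 77), 18 (17 and 1) and 104 (100 and 4), 1 list at 7 dpi, miR-1280 at -0.38, miR-3196 at 0.35 and miR-1469 at 0.086. Scaling to 5S rRNA gave 81 (10 and 71), 17 (15 lower) and 58 (45 higher), 1 list at 7 dpi and miR-1280 at -0.31. Scaling to spike-in probes gave 101 (2 and 99), 139 (1 and 138) and 59 (54 lower), 1 list at 7 dpi, miR-1280 at -0.72, miR-17/92 at -0.71 and the leukocyte list at -0.53 at 21 dpi.

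Subtraction of the empty-spot median with a floor of 32 gave 34 (13 lower), 17 (7 and 10) and 42 (20 higher), and 1 list at 7 dpi. An offset of 16 gave 39 (13 lower), 12 (6 and 6) and 37 (13 higher). The authors' values gave 7 lower at 7 dpi, 15 (5 and 10) at 21 dpi and 1 list between the injured hearts. The brighter part of miRNAs detected on both arrays gave 11 (8 higher), 3 (1 lower) and 12 (7 lower), and 1 list in each comparison. Counting every probe gave 10 and 5 lower at 7 and 21 dpi. A 1.5-fold threshold gave 52 (32 and 20), 30 (16 and 14) and 47 (20 and 27). The median of spots gave 1 higher and 6 lower at 21 dpi. With no detection filter 0 lists lay outside at 21 dpi and 3 between the injured hearts. Detection on both arrays gave 3 (1 lower) at 21 dpi and 15 (9 lower) between them. Removal of the GC trend gave 14 (3 and 11) between the injured hearts. Merging near-identical probes left 0 lists outside at 7 dpi, where miR-15/16 was reversed to 0.31, and 2 at 21 dpi, without miR-17/92.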

Other observations

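Some miRNA groups outside the fixed lists were chosen after their values were seen. The clustered pair miR-221 and miR-222, known from proliferating cells and vessel walls, stood above the uninjured heart at 7 dpi, at 0.65 ± 0.07 and 0.42 ± 0.13, but stood at -0.66 and -0.73 with no normalization. The miR-148 pair stood below the uninjured heart at 7 dpi, with miR-148a at -0.63 ± 0.08, and at 21 dpi at -0.20 ± 0.08 for miR-148a and -0.30 ± 0.07 for miR-148b, which became 0.25 and 0.13 with no normalization. Scaled to the median of shared miRNAs, miR-148a and miR-148b were at -0.19 and -0.17 at 7 dpi and at -0.11 and -0.22 at 21 dpi, so the order of the times depends on scaling for miR-148b. Before normalization, the ratios of miR-148b above the empty spots were -2.28 at 7 dpi and 0.17 at 21 dpi, beside medians of -1.38 and 0.38. Of the miR-181 family, miR-181b stood at -0.29 ± 0.07 and miR-181c at -0.25 ± 0.05 at 7 dpi, and at 0.43 ± 0.12 and 0.33 ± 0.10 at 21 dpi, while miR-181a was at -0.32 ± 0.13 and 0.03 ± 0.15. With cyclic loess the 7 dpi values of miR-181b and miR-181c were -0.009 and -0.032. Scaled to the median of shared miRNAs, the same values were 0.82 and 0.73. That scaling followed the offset and also raised dim probes at 7 dpi. Before normalization, the ratios above the empty spots were -1.44 for miR-181b and -1.32 for miR-181c, beside a median of -1.38. From the cartilage-associated miR-140 locus, miR-140-3p was at -0.24 ± 0.08 and -0.48 ± 0.07 at 7 and 21 dpi. None of these was 2-fold apart after the main normalization.

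Replicate spots of 1 probe parted more than 4-fold from their median, among detected probes with a signal above 50, in 2.5% of 160 probes on the uninjured array, 4.73% of 148 at 7 dpi and 8.38% of 167 at 21 dpi. Most of these were single dim spots, 4, 6 and 13 probes.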
